A study of Homo sapiens with 4 samples.

How the data were processed

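Total RNA of human embryonic stem cells was measured on 1-colour Illumina bead arrays, with complementary RNA made by linear amplification and labelled with Cy3, per the labels' protocols. The 4 groups were cells stimulated for 2 h with 100 ng/ml Activin A, cells stimulated for 2 h with 50 ng/ml BMP4, and a separate unstimulated control for each of these experiments. Each control group had 2 arrays, numbered 1 and 2 per the file headers, and each stimulated group had 1 array. The study's design text speaks of biological replicates beside the controls, so the control arrays were taken as separate cultures. The wording leaves open whether it also covers the stimulated groups, and whether each single stimulated array stands for 1 culture or a pool is not given in the sources used here. The 6 arrays carried the same 24350 probes with human identifiers.

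The deposited per-array files give each probe's average signal intensity on a linear scale, the standard deviation of its beads in the same intensity unit, and a detection score between 0 and 1, per the file headers. The submitters' processing notes name BeadStudio 1.5, and its settings are not given in the sources used here. The deposited intensities were neither background-subtracted nor scaled across arrays, as their lowest values lay between 127.3 and 187.4 and their medians between 230.0 and 304.9. Such a background makes a fold change of a dim probe smaller than the change of its transcript. The detection score moved in steps of 1 in 775, and a probe was taken as detected on an array at a score of at least 0.99.

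A table of the whole series holds intensities that the authors had processed further, with 1 value per group. Each of its columns followed the deposited per-array signal, or for controls the mean of the 2 arrays, with Spearman correlations of at least 0.99995. The slopes lay between 0.956 and 1.10 and the intercepts between -262.1 and -208.9, so a background had been subtracted and a scaling applied, on a linear scale. The medians of the listed values were 255 and 298 in the Activin A and BMP4 controls, 244 after Activin A and 284 after BMP4. Values under 21 were blank. The scaling method is not given in the sources used here, and the table served as an alternative for single probes only, since 1 value per group allows no test.

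Signals were floored at 16, which changed no value, log2-transformed and quantile-normalised across the 6 arrays. Probes detected on every array of at least 1 group were tested, which kept 11700 probes and left out 12650. The names lysA, pheA, thrB and trpF, which are those of bacterial genes, were taken as array controls and left out of normalisation and tests. Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend in the prior. The p-values were adjusted by the Benjamini-Hochberg method over the tested probes, and an adjusted p under 0.05 counted as a call.

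The 6 arrays left 2 residual degrees of freedom, both from the control pairs, and the prior added 17.8. The stimulated arrays had no replicate, so their spread was assumed to equal that of the controls. All p-values for a stimulation rest on that assumption, and the number of arrays limits the precision. The comparisons were Activin A against its own control, BMP4 against its own control, the difference between these responses, and 1 control against the other. The 2 comparisons with stimulation shared no array.

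Probe identifiers hold the letters GI, a number and a suffix, and neither the files nor the reference table used here (GRCh38.p14) pair those numbers with genes. None of the 24350 identifiers matched a gene symbol or accession of that table. The 20 gene lists fixed before the data were examined, with 525 genes, therefore could not be matched to probes, no list was tested, and no gene or genomic position is named. The meaning of the suffixes S, A and I is not given in the sources used here. The rule fixed beforehand chose probes with a gene symbol by the size of their change, and members of the lists. In its place the probe with the largest rise and the probe with the largest fall among the calls of each stimulation are named, which was decided after the identifiers and the values were seen.

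The procedure was tested on simulated data for the comparison of Activin A with its control, with 200 changed probes and 20 runs. The levels were those of the 11700 probes, and the spreads were drawn from the fitted prior. The model recovered 52.8% of changes of 0.5, 92.7% of changes of 0.75, 97.4% of changes of 1 and 99.7% of changes of 1.5 on the log2 scale. Unchanged probes made up 4.36% of the calls, and no call was made in any run without changed probes. Every simulated array, the stimulated one included, varied independently and with the spread that the model assumes. These rates therefore do not test whether a stimulated array varies like the controls. Unlike the simulated runs without changes, real control arrays of the same group gave some calls when 1 was fitted against the other. In those fits the spread came from the control pair of the other experiment. The alternatives fixed before the data were examined were other scalings, offsets, floors, detection filters and priors, a fit of only the groups compared, other thresholds, each control array left out in turn, and the array number as a block. A background correction by normexp from the detection scores was added after seeing the data, as were leaving out control arrays for the overlap of the responses and a fit with the array number of the controls as a term. Combinations that changed scaling, background, filter and prior together were also fitted once, alongside the first fit. They are not reported, and the setting used throughout is the one fixed before the data were examined.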

Results

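The data describe how the transcript levels of human embryonic stem cells differed 2 h after the addition of a growth factor of the transforming growth factor beta superfamily. Activin A and BMP4 both belong to this family and signal through receptors and SMAD proteins that are partly shared and partly different. The cells, of the line H1 where the line was stated, were grown without serum in N2B27 medium with 20 ng/ml FGF2. Activin A at 100 ng/ml and BMP4 at 50 ng/ml were tested in independent experiments, each with its own unstimulated control of 2 arrays and with 1 stimulated array. The doses differed, so the sizes of the responses refer to these doses.

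Between 43.6% and 46.1% of the 24350 probes were detected on each array, or 10605 to 11236 probes. The median signal was 302.2 and 298.3 on the Activin A controls, 304.9 after Activin A, 271.2 and 255.7 on the BMP4 controls and 230.0 after BMP4. The beads of a detected probe had a median coefficient of variation between 3.32% and 3.69%, relative to a signal that still held the background. Over the 11700 tested probes, Pearson correlations across probes were 0.995 between the Activin A controls and 0.996 between the BMP4 controls. The bacterial control names lysA, pheA, thrB and trpF had signals between 174.1 and 286.9.

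Single arrays showed the size of the responses against the difference between control cultures. No probe differed 2-fold between the Activin A controls, and none did between the BMP4 controls. The Activin A array was at least 2-fold higher than control array 1 at 25 probes and higher than control array 2 at 27 probes, and it was 2-fold lower at 1 probe in each case. The BMP4 array was at least 2-fold higher than each of its control arrays at 11 probes and 2-fold lower at 0 probes.

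**Figure D1:**
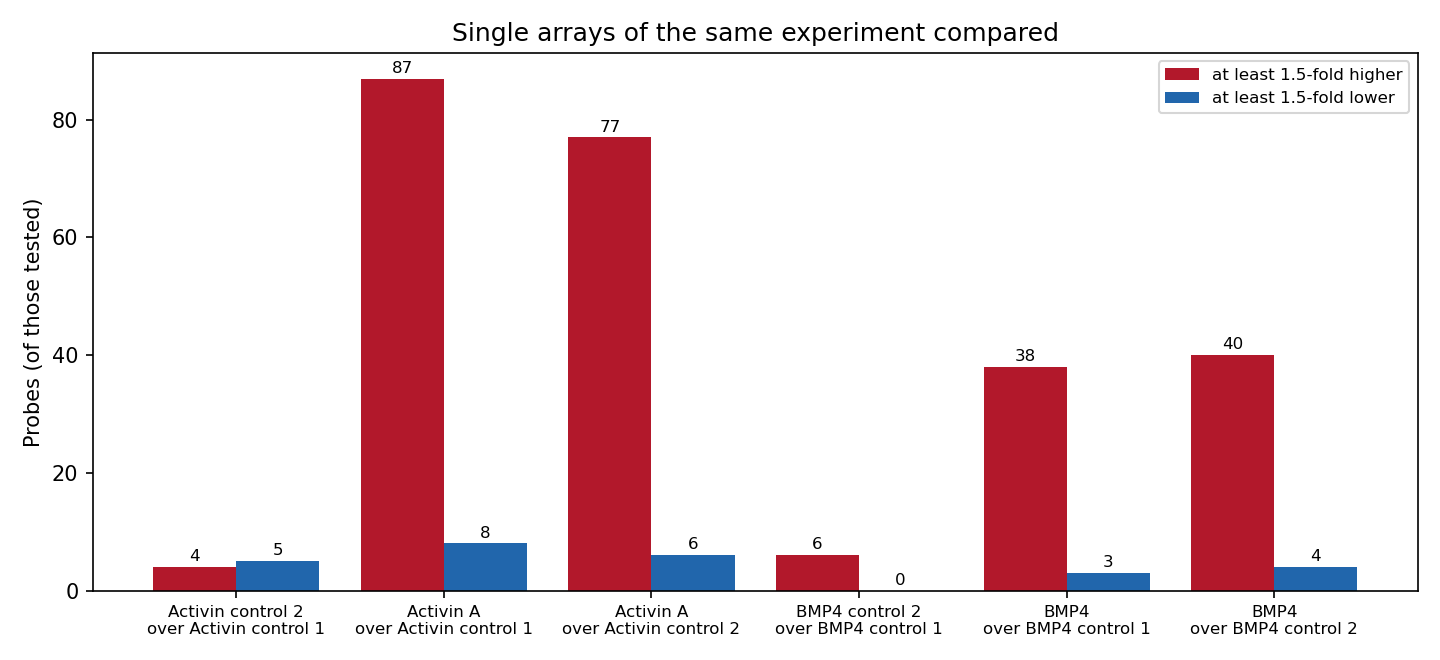
Number of the 11700 tested probes (vertical axis, linear) at least 1.5-fold higher or lower in pairs of single arrays of the same experiment after quantile normalisation (horizontal axis, array named first over array named second). The stimulated arrays exceeded their controls at 77 and 87 probes for Activin A and at 38 and 40 probes for BMP4, against at most 6 probes in either direction between control arrays.

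The comparison of Activin A with its own control asked which transcripts had changed within 2 h. After Activin A, 122 probes rose and 10 fell among 11700 tested (limma, adjusted p under 0.05), which is 1.13% of them. The risers had a median log2 difference of 0.67, or of 1.33 by the authors' background-subtracted table for the 114 of them listed there, and 24 of them rose at least 2-fold, while the fallers had a median of -0.64 and 1 of them fell at least 2-fold. All 122 risers lay above both control arrays and all 10 fallers below both. A value outside both controls on one side or the other occurred at 66.0% of all tested probes.

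The probe with the largest rise, GI_31077201-S, had a log2 signal of 12.27 on the Activin A array against 9.36 ± 0.12 (SD, n = 2) in the control. Its log2 difference was 2.91 with a standard error of 0.12 (limma, adjusted p = 4.52e-12), a 7.50-fold rise. That rank depended on the processing. The rise of GI_4503928-S was 2.79 here, but it was the larger one with normexp background correction (4.19 against 3.43) and in the authors' table (4.31 against 3.47). It was also larger with the lowest signal of each array shifted to 0 and an offset of 50 (3.31 against 3.15). The same held without control array 2 (2.97 against 2.84). The probe with the largest fall, GI_17978496-A, went from 11.82 ± 0.07 (SD, n = 2) to 10.74, a log2 difference of -1.08 with a standard error of 0.13 (limma, adjusted p = 2.56e-05). Of the 122 risers, 99 had identifiers with the suffix S, 17 with A and 6 with I, out of 9580, 1346 and 774 tested. A group of 21 risers was detected on no control array and was detected after Activin A. For these only a lower bound holds, taken against the higher of the probe's own control signal and the lowest detected signal of each control array, and they rose at least 1.03-fold to at least 1.60-fold. The number of calls rose when either control array of the Activin A experiment was left out. The residual spread then came from the BMP4 control pair alone, so that rise does not single out a control array.

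The comparison of BMP4 with its own control asked the same of BMP4. After BMP4, 41 probes rose and 1 fell (limma, adjusted p under 0.05), or 0.359% of the tested probes. The risers had a median log2 difference of 0.76, or of 1.40 by the authors' table for the 37 of them listed there, and 11 of them rose at least 2-fold. All 41 risers lay above both control arrays, while 65.0% of all tested probes lay outside both controls. Of the risers, 34 had the suffix S, 6 had A and 1 had I.

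The largest rise was that of GI_4503928-S, from 9.12 ± 0.08 (SD, n = 2) to 10.91, a log2 difference of 1.79 with a standard error of 0.13 (limma, adjusted p = 4.69e-08). The only probe that fell was GI_31317226-S, from 9.41 ± 0.20 (SD, n = 2) to 8.72, a log2 difference of -0.69 with a standard error of 0.12 (limma, adjusted p = 0.00858). That fall missed the threshold when BMP4 control array 2 was left out (log2 difference -0.54, limma, adjusted p = 0.0729), where the adjusted p over all alternatives ran from 4.47e-07 to that value. A group of 5 risers was detected on no control array and rose at least 1.13-fold to at least 1.53-fold. The Activin A controls entered this fit through the shared spread and the scaling, and without array 1 or array 2 of them the calls numbered 84 or 85. Without any scaling of the arrays the calls were 20 higher and 10 lower, and the median of all tested probes moved to -0.19. Only 21 of the 42 reported calls were among them. Under median scaling they were 64 higher and 4 lower.

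Most probes that rose after BMP4 had also risen after Activin A. The 2 sets of risers shared 32 probes, against 0.428 expected for independent lists (Fisher's exact test, two-sided, p = 1.49e-57, across probes, which are not independent replicates). Both comparisons used the same standard error for each probe, so a probe with a small spread was more easily called in both. The expected number and the p-value ignore this. These shared risers had a median log2 difference of 0.99 after Activin A and 0.83 after BMP4, and 22 of the 32 had the larger value after Activin A. No probe fell after both. Of the 90 Activin A risers that did not pass after BMP4, 74 had a positive BMP4 difference, with a median of 0.18, where 50.0% of all tested probes did. The 9 BMP4 risers outside the shared set included 8 with a positive Activin A difference, with a median of 0.30. Outside the calls the responses had a Pearson correlation across probes of 0.02, against 0.26 over all tested probes and a Spearman correlation of 0.03. Leaving out the calls removes the largest responses. The SD of all BMP4 differences, 0.129, was also close to their median standard error of 0.119. The low correlation therefore does not exclude weaker responses common to both factors. With no scaling the shared risers numbered 18, and without array 1 or array 2 of the Activin A controls they numbered 52 or 53.

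**Figure D2:**
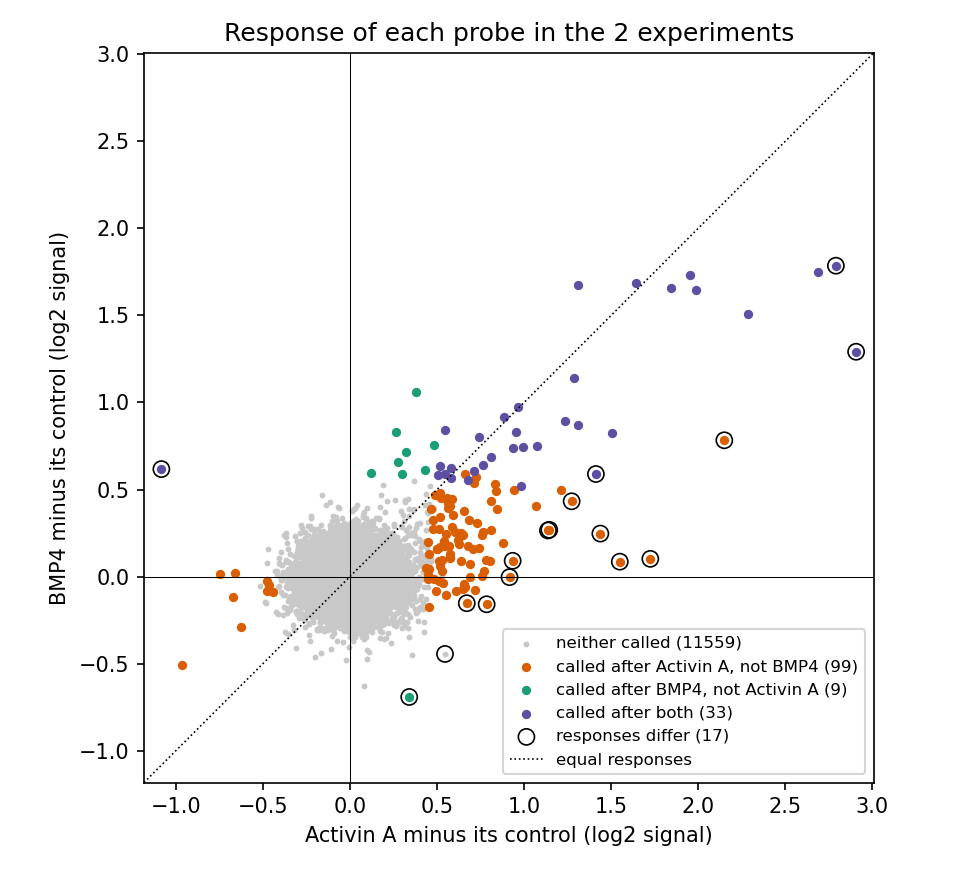
Log2 difference from the own control after Activin A (horizontal axis) and after BMP4 (vertical axis) for the 11700 tested probes, with colours for the calls of each comparison, circles for the 17 probes whose responses differed and a dotted line of equal responses. Of the 33 probes called in both comparisons 32 rose in both and 1 moved in opposite directions.

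The responses themselves differed at 17 probes, of which 16 had the larger value after Activin A and 1 after BMP4 (limma test of the difference, adjusted p under 0.05). Of those 16 probes, 14 had risen after Activin A. Among them, 11 passed after Activin A and not after BMP4, with median log2 differences of 1.14 and 0.10, and 3 had risen after both. The other probes of the 16 were 1 called after neither factor and the probe that fell after BMP4. Both probes with the largest rises belonged to these 3. GI_31077201-S rose by 2.91 after Activin A and by 1.29 after BMP4, a difference of 1.62 with a standard error of 0.17 (limma, adjusted p = 4.47e-05). Its level was 0.49 higher in the Activin A control than in the BMP4 control (limma, adjusted p = 0.00847). GI_4503928-S rose by 2.79 and 1.79, a difference of 1.01 with a standard error of 0.18 (limma, adjusted p = 0.0316). Its control levels differed by -0.71 (limma, adjusted p = 0.000592), the BMP4 control being higher, while its log2 signal was 11.20 after Activin A and 10.91 after BMP4. With normexp background correction its Activin A rise was 18.3-fold in place of 6.92-fold, and the difference was larger, at 1.85, with an adjusted p of 0.0518 in limma, the highest over the alternatives, of which the lowest was 2.14e-06. The BMP4 rise of GI_31077201-S was 3.74-fold with that correction in place of 2.45-fold.

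GI_17978496-A was the single probe called in opposite directions. It fell by 1.08 after Activin A and rose by 0.62 after BMP4 (limma, adjusted p = 0.0345), and the responses differed by -1.70 with a standard error of 0.18 (limma, adjusted p = 4.47e-05). Its level was also 1.10 higher in the Activin A control than in the BMP4 control (limma, adjusted p = 3.28e-06). The BMP4 rise missed the threshold with no scaling (log2 difference 0.45, limma, adjusted p = 0.113) and without BMP4 control array 1 (0.56, adjusted p = 0.165), while the lowest adjusted p over the alternatives was 0.000454. GI_31317226-S fell after BMP4 and had a log2 difference of 0.34 after Activin A that did not pass (limma, adjusted p = 0.376), while the responses differed by 1.03 with a standard error of 0.18 (limma, adjusted p = 0.0202). That difference was 1.69 with normexp background correction and 1.79 in the authors' table. Of the 9 BMP4 risers outside the shared set, only GI_17978496-A passed the test of the difference. The count of 17 became 52 and 58 without array 1 or array 2 of the Activin A controls, and 30 without array 1 of the BMP4 controls. It was 54 without any scaling, 8 with normexp background correction and 8 with the lowest signal of each array shifted to 0 and an offset of 50.

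**Figure D3:**
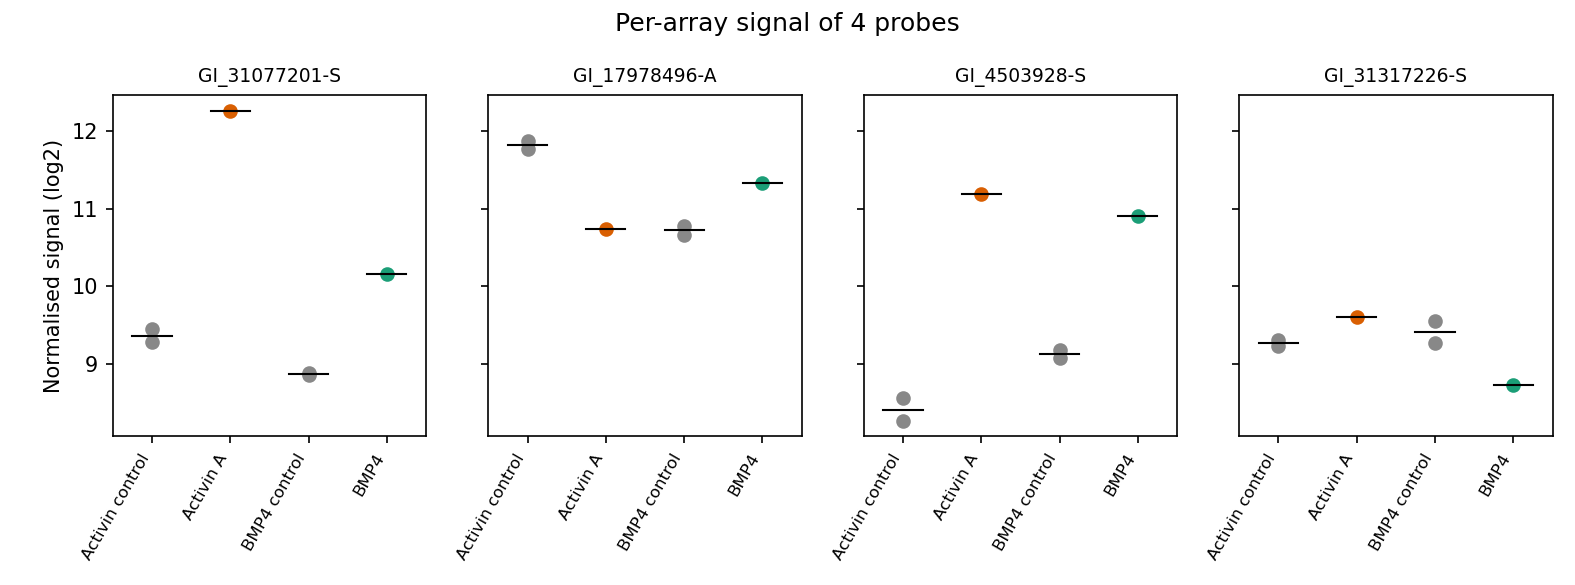
Quantile-normalised log2 signal (vertical axis) of the 4 named probes on each of the 6 arrays (points), by group, with the group mean as a line. GI_31077201-S and GI_4503928-S lay above both controls after either factor, and GI_17978496-A moved in opposite directions.

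The unstimulated controls of the 2 experiments also differed. Between them 311 probes passed, of which 148 were higher in the Activin A control and 163 in the BMP4 control (limma, adjusted p under 0.05). The median log2 difference of the called probes was 0.45 and -0.46, and the most extreme values were 1.52 and -2.32. More probes were called between the controls than after either factor, but 6 of them differed at least 2-fold, against 25 called after Activin A and 11 after BMP4. This comparison had 2 arrays on each side and a median standard error of 0.10, against 0.12 for a stimulation. With the array number as a replicate block 1176 probes were called (570 higher and 606 lower), the 311 included. What an array number marks is not given in the sources used here. Of the 311 probes, 27 were also called after Activin A and 9 after BMP4, and 9 were among the 17 probes whose responses differed. These comparisons share the control arrays, so their calls can coincide without any other link. The split of higher and lower calls depended on the scaling, with 267 and 590 without any and 114 and 5735 under median scaling, where the median of all tested probes moved to -0.23. The count was 622 without array 1 of the Activin A controls, and 201 and 140 without array 1 or array 2 of the BMP4 controls.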

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

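The tests of the scaling, of a signal-dependent shift and of the act of stimulation were chosen after the results they bear on had been seen, and so were the rules by which the tests of the act of stimulation and of falls near the background stay open. The responses to Activin A and BMP4 differed at 17 probes by the test of the difference. Among them were the named probes GI_31077201-S with 1.62, GI_17978496-A with -1.70, GI_4503928-S with 1.01 and GI_31317226-S with 1.03, as the Activin A response minus the BMP4 response on the log2 scale.

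The set of 32 probes that rose after both factors was weighed against technical explanations. Removing a difference between array numbers common to both experiments left the median BMP4 response of the shared risers at 0.83, before and after. That removal decides little. No tested probe differed 2-fold between control arrays, and a large difference between them makes a call less likely, so the median could hardly have changed. A signal-dependent shift of the single stimulated arrays was examined in the unscaled signal. There the shared risers had a median response of 1.04 after Activin A and 0.70 after BMP4. The 20 tested probes nearest to each riser in control signal had a median response of at most 0.31 after Activin A and at most 0.14 after BMP4. That comparison also decides little. The risers were called after quantile normalisation, which removes a shift common to probes of like signal. They were thus chosen for lying above such probes. The spread between control cultures was argued against by fits of 1 array against 1 array, with the spread taken from the control pair of the other experiment, in which control arrays in the place of stimulated ones gave at most 2 shared probes, against 30 to 35 for the stimulated arrays. The control fits called few probes in all, and in some of them calls were shared. A shared call can thus arise with no factor added. The act of stimulation, such as a change of medium, may account for part of the set of 32. It cannot be told apart from a response common to both factors, because no mock-stimulated array was analysed here. Of the 32 probes, 7 differed between the responses when the test was adjusted over these probes alone, which does not decide this, since handling may also have differed between experiments. A first reading of that test had excluded this explanation and was withdrawn for that reason.

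Rises outnumbered falls, with 122 against 10 after Activin A and 41 against 1 after BMP4. For Activin A, falls were at most 0.0473 times as many as rises under median scaling or no scaling. The median of all tested probes moved up there, to 0.04 and 0.06. Those shifts were small beside the smallest called difference of 0.44, but both favour rises. The low ratio therefore does not exclude the scaling between arrays as part of the reason. For BMP4 it stays open, since falls were 0.5 times as many as rises without scaling (10 against 20), where the median of all tested probes moved to -0.19, while under median scaling 4 fell and 64 rose. The excess after Activin A was smaller without 1 of its control arrays, with 51 falls against 177 rises without array 1 and 75 against 196 without array 2. Falls hidden near the background could explain part of the excess after Activin A. Among probes at 4 times the background level or more, falls were 0.214 times as many as rises (6 against 28), a share of falls of 17.6% with an exact 95% interval from 6.76% to 34.5%, and among the other probes 4 fell and 94 rose (Fisher's exact test, two-sided, p = 0.0185). The ratio lay under the bound of 0.25 set beforehand for excluding this explanation, but by less than its spread, so the explanation stays open. No biological explanation was tested.

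The controls of the experiments differed at 311 probes. Noise of single control arrays was argued against as the whole cause, because 87.8% of these probes (273 of 311) had the same sign between the 2 stimulated arrays, which share no array with the controls. The size was smaller there, with a median log2 difference of 0.34 against 0.45 for probes higher in the Activin A control and of -0.17 against -0.46 for probes higher in the BMP4 control. Array batch and culture cannot be told apart for these 311 probes, since each experiment had its own arrays and its own cells.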

How the results depend on the processing

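Of the alternative counts, 41 lay within 1.5 times the reported count and 31 did not. This compares numbers of calls only, and a similar count can hold other probes. The normexp correction, leaving out control arrays for the shared calls, and the array number as a term for the stimulations were chosen after seeing the data. The cause was not tested unless the construction of an alternative is named. Without scaling, the probes whose responses differed numbered 54, those between the controls 857 (267 higher and 590 lower, against 148 and 163) and the shared calls 19. The BMP4 calls then split into 20 higher and 10 lower, against 41 and 1, and held 21 of the 42 reported calls. Median scaling gave 68 BMP4 calls and 5849 between the controls (114 higher and 5735 lower). The shift with an offset of 50 and the normexp correction each left 8 probes whose responses differed. A fit of only the groups compared gave 84 BMP4 calls. An unadjusted p under 0.001 gave 64 BMP4 calls and 39 probes whose responses differed. A 2-fold minimum, which removes small changes by construction, left 25 Activin A calls, 11 BMP4 calls, 8 probes whose responses differed and 6 between the controls. Leaving out each control array in turn gave 144 to 271 calls for Activin A, 40 to 85 for BMP4, 18 to 58 for the difference, 140 to 622 between the controls and 31 to 53 shared calls. In these fits a lone control array was assumed to vary like the other groups. The differences between control arrays 1 and 2 correlated between the experiments across probes (Pearson r = 0.38), and with the array number as a replicate block the controls differed at 1176 probes (570 higher and 606 lower), the 311 included. No paired analysis was possible for the stimulations because each stimulated group had 1 array with no array number. With the number of the control arrays as a replicate block and the stimulated arrays assumed to lie midway, 264 probes were called after Activin A, 77 after BMP4 and 50 for the difference, the reported calls included, and 54 calls were shared. The log2 differences were unchanged by construction, and 1 residual degree of freedom remained. No named probe changed direction under the alternatives run. Under the floor, the filters, the prior without a trend, the fit of only the groups compared and the block, none could. These settings left the log2 differences of the named probes unchanged. In 163 values of the named probes, those settings included, the direction and the side of the threshold were kept. In the value table, which has no test, a kept value lay within 1 standard error. Another 9 values of that table lay farther off, and 4 calls were lost (named with the comparisons). A kept call could differ in size: with normexp the BMP4 fall of GI_31317226-S was -1.19 against -0.69. The floor at 32 changed no value. The gene list tests were not run because no probe could be matched to a gene, nor counts from the value table, with 1 value per group, nor a fit of only the groups compared for the difference, which uses all groups. The background in the signal limits the folds. The risers' medians from the authors' table were larger, but that table was also scaled and lists fewer of the risers. The gap therefore cannot be credited to the background alone.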

Other observations

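The tests of identifiers here were chosen after the results were seen and were extended after a first look. Probes whose identifiers hold the same number moved together to some extent. Over 126 pairs of tested probes with the same number, the Spearman correlation of the Activin A differences was 0.40 (permutation p = 5e-04, one-sided, the smallest that the 2000 draws can give, adjusted 0.002 over 4 relations), and that of the BMP4 differences was 0.19 (permutation p = 0.0185, adjusted 0.022). No such pair had both probes called higher.

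Risers also had neighbouring identifiers more often than random pairs. Among 3948 pairs of tested probes with numbers 1 or 2 apart, 4 pairs were both called higher after Activin A, against a mean of 0.445 over 10000 random pairings (permutation p = 0.0011, one-sided, adjusted 0.0034 over 4 relations). After BMP4 there were 2 such pairs, against a mean of 0.0706 (permutation p = 0.0017, adjusted 0.0034). Why was not tested, and the counts of pairs are small. A probe could belong to 2 neighbouring pairs, which the random pairings did not keep, so these p-values are approximate. The counts for the 2 factors are not separate evidence, as 32 of the 41 BMP4 risers had also risen after Activin A. Across all such pairs the Spearman correlation of the differences was 0.03 for Activin A and 0.05 for BMP4.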
